A study of Macaca mulatta with 13 samples.

How the data were processed

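Single-cell RNA was measured in leukocytes from the colon of rhesus macaques (Macaca mulatta), in a transplant model of acute graft-versus-host disease (GVHD), in which T cells of the donor attack tissues of the recipient. Per the labels' protocols, 4 colon samples came from the transplanted cohort and 4 from untransplanted controls, and viable cells positive for CD45, a surface protein of leukocytes, were sorted. In 2 of the GVHD samples the sort also parted host from donor cells by MAMU-A001, a macaque MHC class I molecule, and in 2 others host and donor cells were told apart by computation. Sorted cells were also negative for the CD45 label that the protocols mark IVas. Libraries were made with versions 2 and 3 of the 10x Genomics droplet kit and sequenced on a NovaSeq. The labels name 13 libraries, of which 4 are host fractions, 2 are donor fractions, 3 hold host and donor cells together and 4 are healthy controls. Which kit made which library is not given in the sources used here.

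The deposited raw matrix holds counts of unique molecular identifiers (UMIs), each of which marks 1 captured RNA molecule, per gene and barcode. It was made with Cell Ranger 3.1.0, per the file headers and the submitters' processing notes, and the genome build and annotation are not given in the sources used here. The matrix has 34628 genes and 57086 barcodes with 146797955 UMIs in all. A further matrix deposited by the authors holds the natural log of 1 plus a corrected count for 20606 cells that they kept. Its 24884295 entries all became whole numbers (tolerance 1e-06) after the log was undone. The corrected counts have totals less spread than the raw ones, with a ratio of the 97.5 to the 2.5 percentile of 3.27 against 11.7 in the same cells. Seurat 3.1 is named in the submitters' processing notes without a role, and the step that corrected the counts is not given in the sources used here. Tested on the raw counts, every kept cell had at least 800 genes and over 1500 UMIs, 1 barcode over both limits was not kept, and the 17426 kept genes were those found in at least 5 kept cells. Kept cells hold 74.8% of all UMIs. The corrected values served only to find which cells and genes the authors kept, and all levels below come from the raw counts. Of the gene IDs, 23811 carry a symbol in the file and 695 more took one from the table of gene names used here, while 24126 IDs matched that table. No mitochondrial gene carries a symbol, so no mitochondrial share was computed.

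Each barcode ends in a number from 1 to 13, and which label a number belongs to is not given in the sources used here. The plan made before the data were examined foresaw this case. The cells were treated as 1 pooled sample, classes and clusters were described, and values were given for each barcode number as an unassigned library. The planned comparisons of donor with host fractions and of each GVHD group with the healthy controls, by summed counts, gene lists and cell shares, were therefore not computed, and no p-value is given. Libraries 4 and 6 share 5323 barcodes where 39.3 would be shared at the rate of the other pairs of their barcode set, and were counted once, which leaves 20567 cells in 12 libraries. This was decided after the barcodes were seen.

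Clustering used scanpy 1.11.5 on the kept cells. Counts were scaled to 10000 per cell and put on a log scale, 2000 variable genes were scaled to a highest value of 10, and 30 principal components with 15 nearest neighbours gave a graph weighted by shared neighbours. Leiden clustering ran at resolution 1 with seed 0. The libraries entered only the choice of variable genes, and no correction for library or kit was applied. This graph replaced the tool's default after a first run, so that clusters would come out alike on every run. Scrublet scores in the 10 libraries with at least 200 cells called 59 cells (0.286%), too few for the caller to have worked, so no cell was removed as a doublet. A first test for pairs of a plasma and a T cell, by the gathering of T markers in single droplets, gave 0.989 where 1.26 was the highest value possible, and was replaced after it was seen.

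Clusters were named from marker genes fixed before the data were examined. Levels are in CPM, the usual scaling of a gene's UMIs by all UMIs of the same cells. A marker's value is its CPM over its highest CPM in any cluster, and the score of a class is the mean over its markers. A class needed 3 markers of at least 10 CPM and a score 25% above the next class, and each of its first 3 markers had to reach 10% of its highest CPM. CD3E and CD3G at 15% of their highest CPM excluded NK or innate lymphoid cells, and MS4A1 and CD79A did so for plasmacytoid dendritic cells. A cluster stayed unnamed where another class had 2 more markers among its 10 leading genes than its own class. These thresholds were the last of 5 versions, set after the calls and the shares of earlier versions were seen, while the markers stayed as fixed. A T-like cluster is CD8 T-like where CD8A and CD8B are both above the mean of the other T-like clusters and CD4 is not. The marker genes KLRC3, IGHA, FKBP11, TPSAB1, TPSB2, LILRA4, KRT8, MUC2, HBA, HBB and UBE2C were not matched by symbol.

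CD8 T-like cells were compared with the other T-like cells inside each library that has at least 20 cells of both kinds. Counts were summed per library and kind, turned into CPM and compared as log2 ratios after 5 CPM were added to both, which understates the ratio of low genes. CPM are pooled over all T-like cells of a kind, those of the other libraries included. The median over libraries is given with the lowest and highest library, and a gene was measured at a mean of 5 CPM. A gene list has the median of its members, with its percentile among 10000 random lists of as many genes from the same of 20 expression bins. Of 19 lists fixed before the data were examined, the mitochondrially encoded and haemoglobin lists had no measured member. The genes named are the 10 leading genes of each cluster by fold (at least 50 CPM), the fixed markers, up to 4 members of each list with the largest medians, and genes fixed before the data were examined, among them ITGAE, CD69, GZMB, CD8A, CD4, FOXP3, IFNG, CCR7 and MKI67. Genes with the largest medians among those that went one way in every library were also named. Intervals of shares are Wilson intervals and those of CPM are exact Poisson intervals, at the 95% level, and cover counting error only. Shares of cells with a UMI were also computed after each cell was thinned to 1500 UMIs.

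The comparison was tested on simulated data with the real levels and library sizes of the 8 libraries, 7951 genes and 200 changed genes. All changed genes came out in the right direction. They went one way in every library in 34.3%, 53.7% and 78.8% of cases at true log2 changes of 0.5, 1 and 2, against 0.593% of unchanged genes. The simulation kept the 2 kinds as given and did not cluster anew, so this is no null value for kinds that come from clusters. It also had counting noise only, with the same true change in every library. These rates therefore do not cover real spread between libraries or cells. A list raised by 1 was found at 0.99, and unchanged lists lay between -0.07 and 0.03. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, anndata 0.12.19 and matplotlib 3.10.9.

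The same values were also computed with Leiden resolution 0.5, all raw barcodes with at least 500 UMIs and 300 genes, cells thinned to 1500 UMIs, and each library left out. These choices were made before the data were examined, and 10 more were added after. The added ones are the removal of called doublets, an unweighted graph, 4 other versions of the naming, both copies of the repeated library, a gate on CD8A and CD4 in place of clusters, and each barcode set alone.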

Results

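The data are UMI counts of single leukocytes sorted from the colon of rhesus macaques with GVHD after transplantation of blood-forming cells and of untransplanted controls. By its title the study concerns how donor T cells become resident in the gut, which the labels address by host and donor fractions and healthy controls. Which barcode number belongs to which group is not given in the sources used here, so the values below describe the pooled cells and the unassigned libraries, numbered by their barcodes. No comparison between the label groups was made. The libraries held between 3128386 and 19655788 UMIs and between 1277 and 5971 barcodes. The 12 libraries counted once had from 29 to 2858 kept cells, with a median of 3412 UMIs and 1144 genes per kept cell over all kept cells.

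T-like cells were the largest class in the colon leukocytes. They made up 57.3% of 20567 cells (95% interval 56.6 to 57.9), B-like cells 24.1% (23.5 to 24.7) and plasma-like cells, the antibody-secreting cells, 12.3% (11.9 to 12.8). Myeloid-like cells made up 1.35%, epithelial-like cells 0.870% and stromal or endothelial-like cells 0.297%, and 3.79% of cells stayed unnamed. These small shares hung on single libraries and on the clustering made anew without them. Epithelial-like cells were 0.295% without library 1 and 1.43% without library 7, and 2.76% over all barcodes. Myeloid-like cells were 0.892%, 0.867%, 0.783%, 0.7002% and 0.762% without libraries 2, 3, 4, 12 and 13. Unnamed cells were 2.22%, 2.17%, 0.756% and 0.828% without libraries 1, 4, 5 and 9, and from 0.734% in thinned cells to 27.2% with naming by score alone. The spread between libraries was far wider than these counting intervals. Among the 11 libraries with at least 100 cells, T-like cells ranged from 16.7% in library 3 to 86.2% in library 2 (median 59.7%), B-like cells from 0% to 77.9% (median 1.75%), and plasma-like cells from 0% to 78.3% (median 10.0%). Library 6, with 101 cells, had no cell named B-like or plasma-like, while 22.8% of its cells stayed unnamed. Epithelial-like and stromal or endothelial-like cells, which a CD45 sort should remove, made up 27.7% and 19.8% of it. Unnamed cells were between 0.275% and 26.7% of a library, and their share follows the naming thresholds, which were set after the data were seen. Among them, cluster 15 (450 cells, 50.4% of them from library 5) scored 0.616 as plasma-like against 0.038 for the next class. The plasma-like shares leave this cluster out, so they are likely too low, above all in library 5 and in library 3, which gave 22.9% of the cluster. The lowest share of 0% also rests on this naming.

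**Figure D1:**
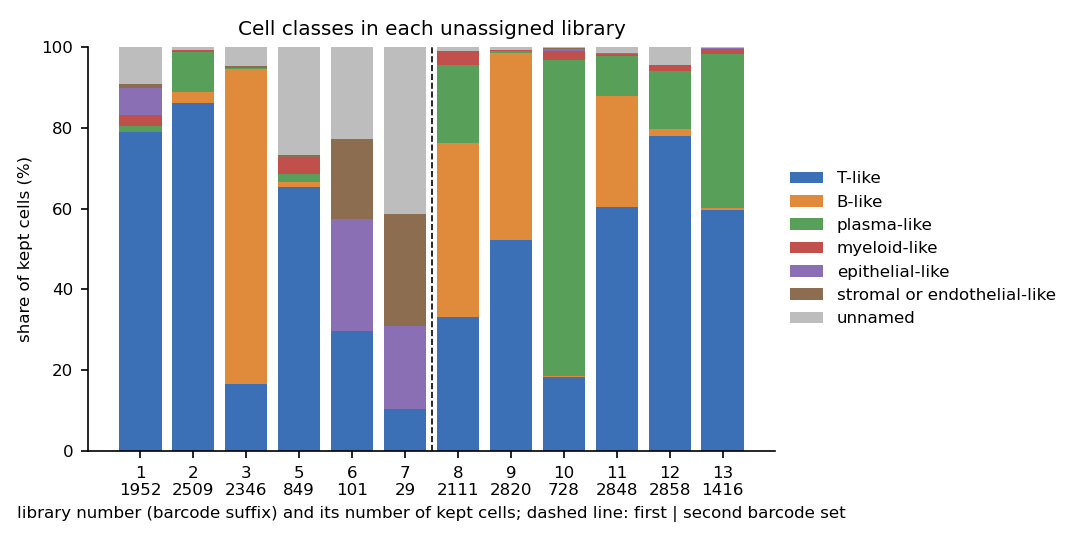
Bars give the share of kept cells in each class (percent, vertical axis) for the 12 libraries counted once (horizontal axis, with the number of kept cells). The T-like share runs from 10.3% in library 7, which has 29 cells, to 86.2% in library 2, and B-like cells reach 77.9% in library 3.

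The T-like cells divided into 12 clusters, which differed in granzymes, homing receptors and helper genes. The clusters were built from the same genes, so these levels describe them and are not findings about them. CD8 T-like cells were 35.2% of T-like cells (34.3 to 36.0) and lay in clusters 1, 8, 13 and 18. Cluster 1 (2018 cells) was led by TNFSF14, CRTAM, the cytokine gene IL22 (87.9 CPM) and ITGA1, the alpha chain of a collagen-binding integrin (328 CPM). Cluster 8 (1043 cells) was led by the chemokine genes XCL1 (384 CPM) and CCL5 (5694 CPM). Cluster 13 (732 cells) was led by GZMM, GZMK, GNLY (5328 CPM) and the pore-forming PRF1 (254 CPM), and cluster 18 (347 cells) by IGFBP2, GZMK (2619 CPM) and EOMES, a transcription factor of cytotoxic cells.

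Among the other T-like clusters, cluster 5 (1194 cells) had the genes of naive and recirculating T cells, with the transcription factor gene LEF1 at 70.8 CPM and CCR7, which encodes a lymph node homing receptor, at 327 CPM. Cluster 2 (1383 cells) was led by CD40LG (113 CPM), the helper ligand for B cells, and IL7R (2311 CPM), and cluster 3 (1322 cells) by OLFM4, KLRB1 (469 CPM) and ICOS (389 CPM). Cluster 4 (1217 cells) was led by TNFRSF4 (639 CPM), TNFRSF18, GATA3 and CTLA4 (481 CPM), which are known from activated and regulatory T cells, yet it had FOXP3 at 3.29 CPM. Cluster 9 (994 cells) was led by CCL20 (1751 CPM), TOX2 and IL21 (169 CPM), a cytokine of T cells that help B cells. Clusters 11 (816 cells) and 16 (388 cells) held the most GZMA (12066 and 14112 CPM) and GZMB (12488 and 14250.4 CPM), with CD4 at 87.5 and 78.7 CPM and CD8A at 75.4 and 298 CPM. Cluster 16 was also led by PRF1 (506 CPM) and by the cell division genes RRM2, CCNA2 and TYMS, with MKI67 at 307 CPM. Cluster 19 (324 cells) was led by the receptor genes KIR2DL4 and KLRD1 with GNLY at 5486 CPM, and had CD8A at 303 CPM beside CD8B at 10.3 CPM and CD3E at 593 CPM. GNLY, KIR2DL4 and KLRD1 are also genes of NK cells, which are not excluded among its cells.

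**Figure D2:**
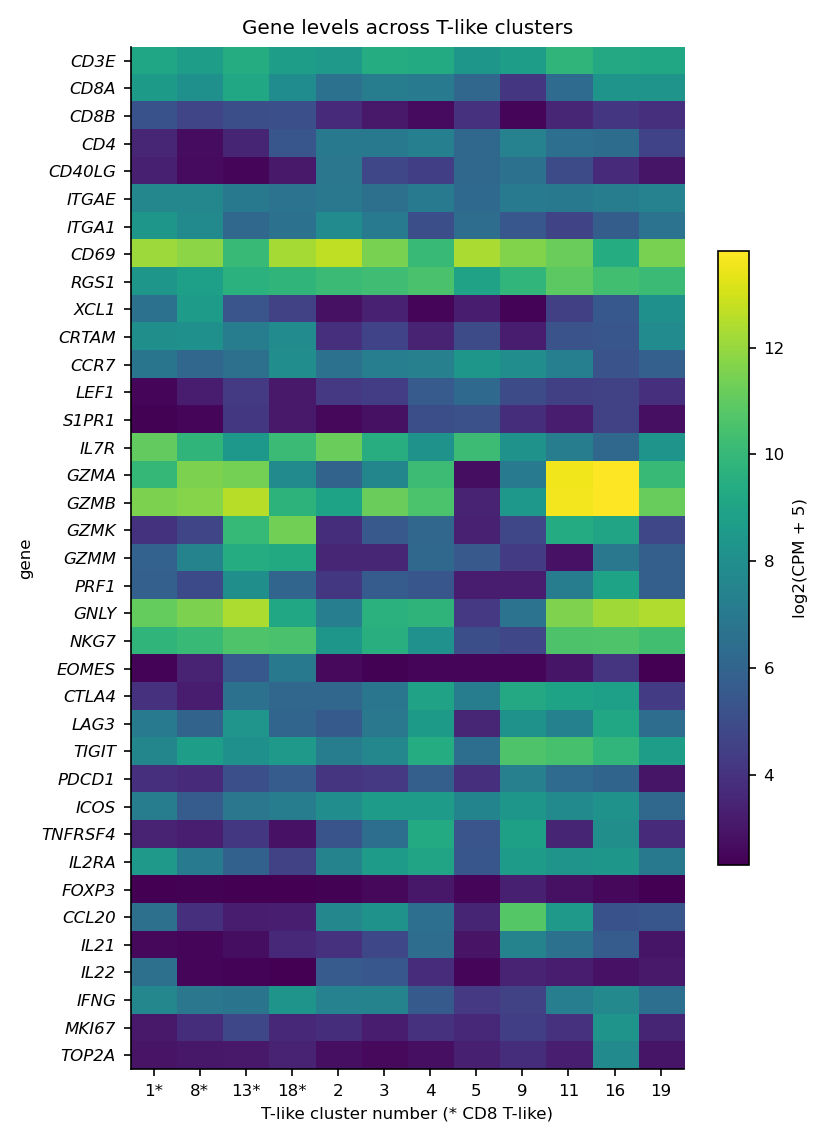
Colour gives the level of each gene (rows) as log2 of CPM plus 5 in each T-like cluster (columns, CD8 T-like clusters marked by a star). GZMA and GZMB are brightest in clusters 11 and 16, where GZMB reaches 12488 and 14250.4 CPM, and LEF1 in cluster 5, at 70.8 CPM.

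Few clusters were shared evenly by the libraries. Of 28 clusters, 26 took at least 90% of their cells from one of the 2 sets of libraries that share barcodes, 12 from the first and 14 from the second, and 9 took at least 80% from a single library. The exceptions were the dividing T-like cluster 16, with 86.1% from the first set, and the myeloid-like cluster 21, with 40.1%. Of the 12 T-like clusters, 11 took at least 90% of their cells from one set. As no correction for library was made, leading genes can mark libraries as well as cell states. IL7R, a leading gene of cluster 2, was at 58.9 to 634 CPM in T-like cells of first-set libraries and 766 to 1876 CPM in the second. CD8 T-like cells were 0% to 86.1% of the T-like cells of a library (median 23.2%). In the first set the median was 1.95% over 5 libraries, and in the second 48.0% over 6. This share follows the rule for whole clusters and not CD8A alone, since cluster 19, with 70.7% of its cells from library 1, counts as other for its low CD8B. T-like CD8A was at 165 CPM in library 1, where 1.95% were CD8 T-like, and 164 CPM in library 8, where 37.1% were. The CD8 T-like clusters also drew their cells from different libraries, with 84.6% of cluster 1 in library 12, 52.5% of cluster 8 in library 13, 91.9% of cluster 13 in library 2 and 57.1% of cluster 18 in library 11.

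CD8 T-like cells had more RNA of several killing genes and of CCL5, a chemokine of activated killer cells, than the other T-like cells. GZMA, GZMB and PRF1, given below, did not go one way in every library. Pooled over all libraries, CCL5 was at 4009 CPM in 4140 CD8 T-like cells and 535 CPM in 7638 other T-like cells. Library 12 gave 1916 of these CD8 T-like cells but 309 of the others, so pooled levels mix library with cell kind. Inside the 8 libraries with at least 20 cells of both kinds, the median log2 ratio of CCL5 was 3.93 (2.10 to 6.89). CRTAM, a receptor of activated CD8 and NK cells, was at 237 against 26.2 CPM (log2 ratios from 1.87 to 4.29). CD160 stood at a median of 3.06 (1.29 to 4.66) and KLRD1, the CD94 chain of NK receptors, at 2.90 (0.62 to 4.95). In contrast TNFRSF4, the costimulatory receptor OX40, stood at -4.67 (-5.30 to -2.92) and CD40LG at -3.41 (-4.01 to -1.65). Of 7830 genes measured, 142 were higher and 316 lower in CD8 T-like cells in every one of the 8 libraries, 5.85% in all, and the median of all genes was -0.05. A gate on CD8A and CD4 in each cell ran over 9 libraries (3 and 5 came in and 10 fell out). It had 113 of the 7830 genes measured higher and 214 lower in all 9, and their overlap with the genes above was not counted. Cells and libraries changed together there, so gated values below are not the effect of the gate alone. As the clusters were built from the same genes, the counts, ratios and percentiles by cluster describe how the 2 kinds differ and are no test of it. CD8A (375 against 124 CPM), CD8B and CD4 (7.26 against 112 CPM) define the 2 kinds and are no finding. The count of higher genes was 411 without library 2, and with the first barcode set alone, which keeps 2 libraries, it was 1350. With fewer libraries more genes go one way by chance alone, so these counts do not compare directly.

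The cytotoxicity list had a median log2 ratio of 1.62 over 14 measured members, above all 10000 random lists, and 5 members were higher and 1 lower in every library. Several of its genes, such as GZMM, GNLY and KLRD1, lead the CD8 T-like clusters, but with the gate on CD8A and CD4 the list was at 1.99, again above all random lists. GZMM stood at 2.34 (1.09 to 4.45), NKG7, a protein of cytotoxic granules, at 2.04 (0.46 to 3.57) and GNLY, which encodes the antimicrobial granulysin, at 1.69 (0.80 to 4.63). GZMK stood at 3.21 but ran from -1.30 to 5.73. GZMB (ENSMMUG00000014381), which encodes the protease granzyme B, was higher in 7 of 8 libraries at a median of 1.53 (-0.47 to 3.49), while its pooled levels were 3527 CPM (3496 to 3559) in CD8 T-like and 3745 CPM (3722 to 3768) in other T-like cells, where clusters 11 and 16 carry it. GZMA ran from -1.63 to 3.86 and was higher in 5 of 8. Markers of NK and innate lymphoid cells were also higher in part, with TYROBP at 1.14 (-1.75 to 4.06, higher in 7 of 8), NCR1 at 9.61 against 1.38 CPM pooled (log2 ratios from -0.57 to 3.48, higher in 6 of 8) and NCAM1 at 0.22 (15.5 against 1.24 CPM pooled). CD3E was at 528 and 566 CPM, and innate cells among the CD8 T-like clusters are not excluded.

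The residency list, genes known from T cells that stay in tissue, had a median of 0.02 over 17 members, at the percentile 86.6 of random lists, and its members went both ways. Of its 20 names, ZNF683 and HOBIT were not matched by symbol, and CXCR6, at a mean of 0.384 CPM, was too low to be measured. CRTAM and NR4A1 were higher in every library and RGS1 lower, at -0.37 (-0.80 to -0.13). ITGAE (ENSMMUG00000008556), which encodes the integrin CD103 that binds E-cadherin on epithelium, was at 173 CPM (166 to 180.3) in CD8 T-like cells and 112 CPM (108 to 116) in the others. Its median log2 ratio was 0.41 (-0.37 to 1.39), higher in 6 of 8 libraries. ITGA1 stood at 0.73 and was higher in 7 of 8, XCL1 at 3.04 (-1.51 to 5.28), RUNX3 at 0.99 and PDCD1 at -1.35. CD69, an early activation receptor that keeps T cells in tissue, was at 3638 and 3155 CPM pooled, with a median of -0.18 (-0.83 to 0.73), and its median changed sign under several alternatives. The list median was -0.15 with the first barcode set alone and -0.10 without library 13, but 0.16 at the percentile 99.99 with the gate on CD8A and CD4, where 3 members were higher and 2 lower in every library.

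The list of circulation and lymphoid homing had a median of -0.48 over 12 members, at the percentile 0.01, and 4 members were lower in every library. These were LEF1 at -2.02 (-2.92 to -1.10), KLF3 at -1.15 (-1.72 to -0.11), S1PR1, the receptor by which lymphocytes leave tissue, at -1.08 (-1.72 to -0.52), and ITGB2 at -0.91 (-2.19 to -0.27). CCR7 stood at -0.56 (-1.57 to 0.44). The list of integrins and adhesion had a median of 0.00 over 14 members, with CD2 at -0.63 and ITGB2 the member lower in every library.

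Helper and regulatory genes lay on the side of the other T-like cells. The regulatory T list had a median of -1.86 over 6 members, below all random lists, with TNFRSF4, CTLA4 at -2.81 (-5.48 to -1.50) and TNFRSF18 at -2.56 (-4.03 to -1.96) lower in every library, and IL2RA at -1.15. FOXP3, the defining factor of regulatory T cells, had 0.147 CPM in CD8 T-like and 1.75 CPM in other T-like cells, so these members stand for the list with next to no FOXP3. The costimulation list had a median of -0.53 over 13 members and 5 lower in every library, among them CD28 at -1.63 (-3.83 to -0.16) and ICOS at -1.53. The inhibitory receptor list had a median of -0.58 over 10 members (-0.34 without library 3 and -0.01 in the first barcode set alone), with CD160 and CD244 (1.65) higher and CTLA4 and BTLA (-1.04) lower in every library. The type 17 list had a median of -1.26 over 10 members, below all random lists, with CCL20 at -3.13 (-5.96 to -0.97), MAF at -2.10 (-2.61 to -0.50) and BATF at -1.43 lower in every library, IL17F at -1.58 and IL22 at -1.59 with libraries from -4.56 to 2.64. The list was 0.37 without library 1, -0.48 without library 2 and -0.84 without library 10, and -0.12 at the percentile 15.8 in the gated cells of 9 libraries.

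Cytokine genes had a median of -0.39 over 8 members, at the percentile 0.06, and from -0.68 with 1 opposing marker enough to -0.07 at Leiden resolution 0.5. IL21 stood at -2.75 (-3.56 to -1.66) and LTA at -0.62, both lower in every library, LTB stood at -1.04 and IL10 at -0.77, and IFNG, the cytokine of type 1 responses, at 0.42 (-0.65 to 2.36). The IFNG median ran from 0.32 to 0.97 with each library left out, and from -0.06 to 1.26 over all alternatives. The chemokine list had a median of 0.26 over 10 members, at the percentile 99.98, with CCL5 and CCL4L1 (2.73, 0.24 to 3.24) higher in every library and CCL3 at 1.22, though reads of CCL4L1 may be split with its near-identical copies. It was -0.09 without library 1 and -0.03 without library 13. The list of MHC class II genes had a median of 1.44 over 4 members, above all random lists, 0.93 without library 2 and 0.80 in the gated cells, with MAMU-DPA1 at 1.72, MAMU-DRB1 at 1.63, HLA-DRA at 1.24 and CD74 at 0.94, and none went one way in every library. In library 12 they lay far on the other side, with MAMU-DRB1 at -4.08, HLA-DRA at -4.40 and CD74 at -2.53.

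Genes of cell division were lower in the CD8 T-like clusters by the list median, but not in cells gated on CD8A and CD4. The proliferation list had a median of -1.05 over 20 members, below all random lists, with 4 members lower in every library, among them TOP2A at -1.92 (-3.90 to -0.11). RRM2 stood at -2.14, BIRC5 at -1.82, TYMS at -1.72 and MKI67 at -1.14 (-3.99 to 0.82). In the gated cells of 9 libraries the list was -0.07, at the percentile 21.8, with no member lower in every library, and with each library left out it ran from -1.62 to -0.67. At Leiden resolution 0.5 the list was 0.96 and MKI67 was 1.79, and the cause was not tested. In the main clustering, cluster 16 had MKI67 at 307 CPM, against at most 23.4 CPM in any other T-like cluster. It counts as other T-like, for its CD8B and CD4, though its CD8A was at 298 CPM. The list median by cluster could thus hang on where this cluster is placed. The interferon list lay near 0, at 0.01 over 20 members and the percentile 80.4, with MX2 at -0.66 and OASL at 0.38 and no member one way in every library. Glycolysis had a median of -0.22 (percentile 0.22; SLC2A3 -0.44, HIF1A -0.42) and apoptosis -0.26 (percentile 0.56; BCL2L11 -1.04). Neither was stable, as glycolysis ran from -0.45 without library 8 to 0.08 at resolution 0.5, and apoptosis was -0.08 without library 5 and -0.14 at the percentile 7.32 in the gated cells. Oxidative phosphorylation had -0.09 (percentile 8.16; NDUFA4 -0.56), and immediate early and dissociation stress -0.07 (percentile 15.5; JUNB -0.92, NR4A1 0.55).

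**Figure D3:**
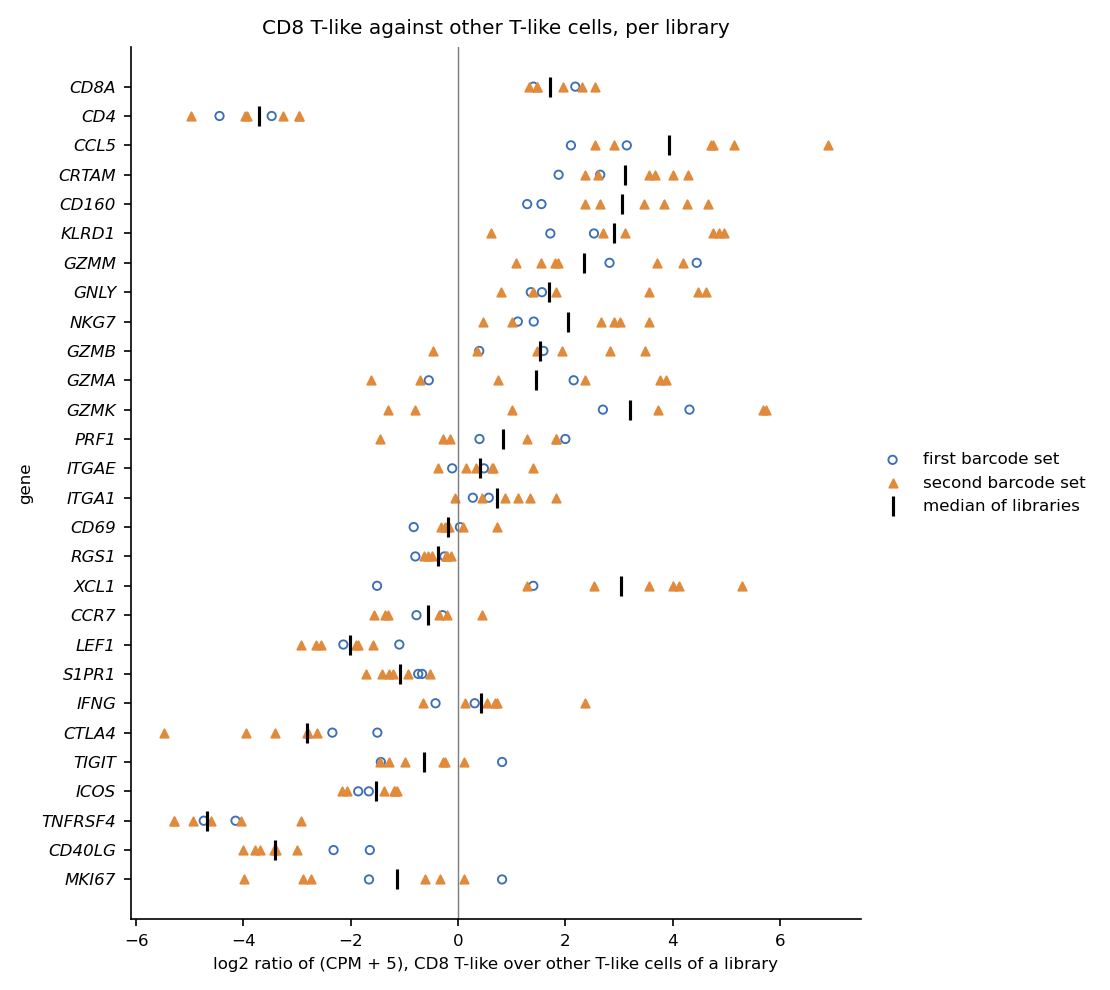
Points give the log2 ratio of CPM plus 5 in CD8 T-like over other T-like cells (horizontal axis) in each of 8 libraries, by barcode set, with a bar at the median. CCL5, CD160 and GZMM lie to the right of 0 in all 8 libraries, at medians of 3.93, 3.06 and 2.34, while GZMB and ITGAE have 1 and 2 libraries to the left.

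Counted by cells with a UMI, ITGAE was seen in 1655 of 4140 CD8 T-like and 2242 of 7638 other T-like cells, but also in 2082 of 4958 B-like and 1115 of 2534 plasma-like cells, at median depths of 3116, 3020.0, 3391 and 11732 UMIs. After thinning to 1500 UMIs the shares were 22.6%, 14.7%, 19.9% and 7.42%, which puts ITGAE in B-like cells between the T-like kinds, where at full depth it was seen in a larger share of B-like cells than of either. All shares of cells with a UMI are pooled over libraries, so they too mix library with cell kind. CD69 was seen in 94.4% and 92.5% of CD8 and other T-like cells and 69.0% of B-like cells. GZMB was seen in 61.3% and 33.4%, against 2.14% of B-like cells, which should lack it. FOXP3 was seen in 2 of 4140 CD8 T-like cells (0.0483%) and 46 of 7638 other T-like cells (0.602%), against 0.0807% of B-like cells. In plasma-like cells, 0 of 2534 had a FOXP3 UMI, and as few cells of any class had one, this sets no limit on how many express it.

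Over all T-like cells, ITGAE ran from 97.0 CPM in library 1 (88.9 to 106) to 186 CPM in library 13 (168 to 205) among the 11 libraries with at least 20 of them (median 125). CD69 ranged from 985 to 5823 CPM (median 3776), CCR7 from 54.9 to 258 (median 127), IFNG from 26.2 to 229 (median 109.9) and CD4 from 25.2 to 242 (median 78.8). GZMB had the widest range in absolute CPM among these genes, from 262 CPM in library 9 to 21532 CPM in library 5 (median 2878). MKI67 ranged from 0 to 188 CPM (median 20.9), CD8A from 25.2 to 316 (median 164) and FOXP3 from 0 to 2.49 (median 0.910). The MKI67 value of 0 is that of library 6, with 30 T-like cells and an upper limit of 40.5 CPM.

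**Figure D4:**
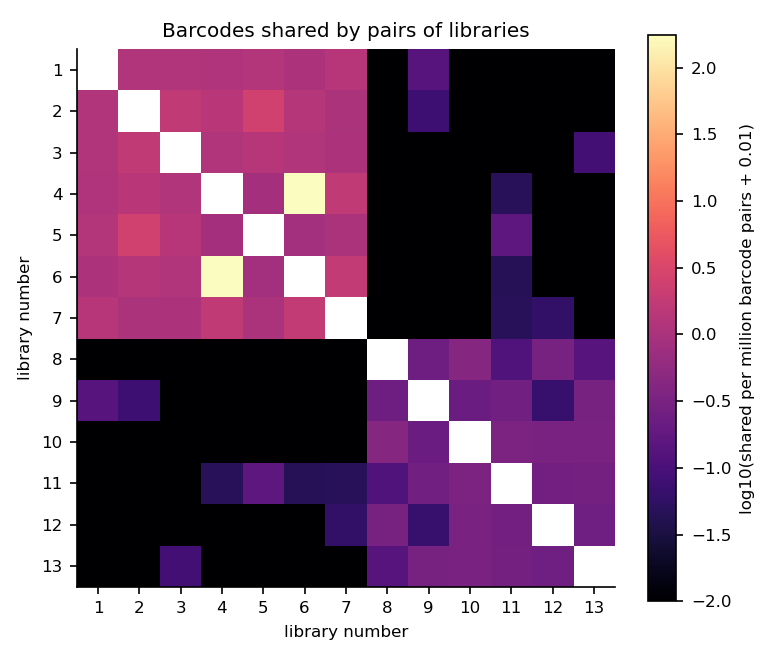
Colour gives how many barcodes each pair of libraries shares, as log10 of the number scaled by the possible barcode pairs. Libraries 1 to 7 and libraries 8 to 13 form 2 blocks, with 6 to 55 and 1 to 10 shared barcodes per pair against 0 to 3 across blocks, and libraries 4 and 6 stand out.

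Barcode sharing parted the libraries into these 2 sets without use of any gene. The 20 pairs within the first set, libraries 4 and 6 as a pair left out, shared 514 barcodes, the 15 pairs within the second set 67, and the 42 pairs across the sets 10. Libraries 4 and 6 shared 5323 of their 5429 and 5558 barcodes. All 39 kept cells of library 4 were among the 101 of library 6, with a median profile correlation across genes of 0.939 for the same barcode (lowest 0.905) against 0.586 for different barcodes (highest 0.744), and these libraries were counted as 1 sample.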

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

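This count of barcodes outside the kept cells was chosen only after the other results were seen. T-like cells were also the largest class among the barcodes that the authors did not keep. Of 17593 such barcodes with at least 500 UMIs and 300 genes, counted once, 9658 fell into T-like clusters, which is 54.9% (54.2 to 55.6), with a median of 1520 UMIs. B-like cells made up 14.3%, plasma-like cells 14.5% and epithelial-like cells 5.13%, and 9.98% stayed unnamed. These T-like barcodes could be true cells, and as their median lies above the limit of 1500 UMIs, many of them missed only the limit of 800 genes. With all such barcodes added the B-like share was 19.4% and the CD8 T-like share of T-like cells 38.6%. Droplets with only free T-cell RNA were not told apart from cells here. The shares of barcodes not kept are pooled and were not broken down by library. Of all barcodes, the authors kept 0.535% in library 7, 1.82% in library 6 and 12.2% in library 10, but 78.6% in library 2. Single libraries can thus weigh much in these shares.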

How the results depend on the processing

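Shares depended most on the naming and on single libraries. T-like cells (57.3%) were 58.5% in cells thinned to 1500 UMIs, 58.2% without called doublets, 50.6% with naming by score alone, 50.2% with 1 opposing marker enough, and 53.4% to 61.9% with each library left out. B-like cells (24.1%) were 19.4% over all barcodes, 4.34% by score alone, 18.6% with an exclusion share of 25%, and 17.2% to 27.7% with each library left out. Plasma-like cells (12.3%) were 14.5% at Leiden resolution 0.5, 14.5% over all barcodes, 14.5% in thinned cells, 14.5% with an unweighted graph, 14.5% by score alone, and 9.87% to 16.7% with each library left out. CD8 T-like cells (35.2% of T-like cells) were 36.7% at resolution 0.5, 38.6% over all barcodes, 36.9% thinned, 37.3% without doublets, 38.8% with an unweighted graph, 29.7% by score alone, 33.0% with 1 opposing marker, and 24.4% to 43.4% with each library left out.

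Genes higher in CD8 T-like cells in every library (142) numbered 94 over all barcodes, 473 with 1 opposing marker, 1350 and 388 in the first and second barcode sets alone, and 121 to 411 with each library left out. Genes lower (316) numbered 175 at resolution 0.5, 515 with 1 opposing marker, 2415 and 582 in the barcode sets, and 295 to 549 with each library left out. Both counts rise by chance alone where fewer libraries are compared, most of all in the first barcode set, which keeps 2. Of 938 values, 818 stayed and 120 moved, among them 94 of 184 shares and 7 of 442 list medians. A share stayed inside its 95% interval, a count within 1.5 times, and a gene or list median inside the range of the libraries, which is wide and lets a median near 0 change sign. Cytotoxicity stayed at 1.17 to 2.09, circulation at -0.97 to -0.28, GZMB at 0.57 to 2.40 and ITGAE at 0.10 to 0.59, while residency ran from -0.15 to 0.58. Of 53 list members and leading genes that went one way in every library, 46 kept their direction throughout, and LAMP1, NR4A1, NUSAP1, STMN1, TOP2A and TUBB did not, while KLF3 came to 0 in one case. Comparisons between the label groups, and the tests planned for them, were not computed.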

Other observations

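The tests for free RNA, doublets, carried-over RNA and cell division below were chosen only after these patterns were seen, while those for the kits and for depth were written before.

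The B-like cells divided into 6 clusters, from resting to dividing cells. Cluster 10 (893 cells) was led by FCER2, a surface receptor of resting B cells (296 CPM), and cluster 6 (1126 cells) by BANK1 with the MHC class II genes MAMU-DRB1 and HLA-DRA (5715 and 7663 CPM). Cluster 14 (720 cells) was led by LMO2 (506 CPM), RGS13 (133 CPM) and MYBL1 (105 CPM), with BCL6 at 96.5 CPM, genes known from germinal centres, where B cells mature. Cluster 17 (371 cells) was led by histone genes such as HIST1H1B, with MKI67, a marker of dividing cells, at 817 CPM and TOP2A at 545 CPM. Library 3 gave 98.7% of cluster 7, led by CD79B and CD74, and 98.9% of the dividing cluster 12, led by CDC20 and AURKB. Their barcode set is the first, while the clusters with the most RGS13 belong to the second.

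Plasma-like clusters 0 (2018 cells) and 20 (315 cells) were led by TXNDC5 (1139 CPM), which folds secreted proteins, and by MZB1 (9023 CPM) with the homing receptor CCR10 (368 CPM). The myeloid-like cluster 21 (277 cells) was led by the genes of inflammatory phagocytes S100A8 (25644 CPM), S100A9, LYZ and IL1B (3302 CPM). Epithelial-like cells in cluster 23 had FABP1 (11373 CPM), PLA2G2A and the gut hormone gene GCG (1649 CPM), and stromal cells in cluster 26 had DCN (20994 CPM) and the collagen gene COL1A1 (3332 CPM). Of the unnamed clusters, cluster 15 (450 cells) held JCHAIN at 85385 CPM and MZB1 at 3412 CPM, which plasma cells express. Cluster 25 (116 cells) held epithelial ZG16 (779 CPM) beside the T-cell gene CD3E (611 CPM). Cluster 24 (169 cells) was led by OLFM4, KIT (187 CPM) and ZBTB16 (148 CPM), and cluster 27 (45 cells) by UTRN. Cluster 24 scored highest as NK or innate lymphoid, at 0.487 against 0.259 for T-like, though it stayed unnamed under the other rules.

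T-like cells of different libraries fell into different clusters, mostly within one of the 2 barcode sets, but their profiles did not part cleanly by set. T-like profiles of one set had a median rank correlation of 0.885 (21 pairs, 4330 genes) and those across sets 0.652 (24 pairs), a difference of 0.233, yet the median was 0.887 in the second set and 0.770 in the first, where libraries 1 and 5 (0.692) were less alike than libraries 1 and 13 across sets (0.813). The hypothesis is that the 2 sets come from the 2 kit versions, whose barcode lists differ, and that part of the gap could come from the kits, which does not account for the spread inside the first set. Animals, disease groups or dates that differ between the sets could do the same and were not tested, since the libraries are not matched to them. Depth is argued against, because thinning every cell to 1500 UMIs left the dependence of cluster on library at 0.99992 times its value.

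Plasma-like cluster 22 (201 cells), led by IGHE, the gene of the IgE heavy chain (979 CPM), carried RNA of T cells. Free RNA spread evenly over the droplets is argued against as the whole source, since the T markers of this cluster, picked for its CD3E, stood at 6.48 to 13.2 times those of the other plasma-like cells of the same 3 libraries (median 6.64). The hypothesis is that many of these droplets could hold 1 plasma cell and 1 T cell. The share of T-cell RNA was 1.08 times that of such a mixture (0.864 to 1.31), and by the median over libraries each of 8 abundant T-cell genes lay within 2 times its expected share, though GZMB was lower in library 10 (7.27% against 23.0%) and higher in library 12 (33.2% against 15.4%). In library 10 the median of 6037.5 UMIs in this cluster lies below the 6914.5 of other plasma-like cells, where such pairs should have more.

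ITGAE, known for T cells bound to epithelium, was about as high in B-like as in T-like cells of 6 libraries. B-like cells had 80.8 to 207 CPM (median 143), and T-like cells a median of 118 CPM and up to 181 CPM. It was higher in B-like cells in 4 of the 6 libraries, though in library 8 only at 115 against 113 CPM, with overlapping intervals. T-cell RNA carried over is argued against, because the ratio of ITGAE to the T-cell gene CD3E was 56.3 times that of T-like cells (31.7 to 75.1). Cell division could explain part, as B-like cells with a cycling-marker UMI had 1.70 times the ITGAE of the others (1.13 to 1.91 in 4 libraries), but the clusters do not follow MKI67 (55.0 CPM in cluster 14, 194 in cluster 12) alone: ITGAE was at 249 CPM in cluster 17, 227 in cluster 14, 194 in the dividing cluster 12, 161 in cluster 7, 92.0 in cluster 10 and 66.4 in cluster 6. B-like cells without such a UMI still had 95.7 to 168 CPM. The integrin gene ITGB7 was higher where ITGAE was lower, at 83.5 CPM in cluster 6 and 37.7 in cluster 10, against 9.95 to 17.3 in the other B-like clusters. No surface protein was looked at, so ITGAE RNA here is no measure of CD103 on B-like cells. Reads shared with HASPIN, which in human lies within an intron of ITGAE and had 26.7 CPM in cluster 17, are another possibility that was not tested.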
